A study of Homo sapiens with 6 samples.

How the data were processed

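Gene expression was measured by 3'-end RNA sequencing in 6 libraries of MDA-LM2 cells, 2 with a control shRNA, 2 with an shRNA against EXOSC10 and 2 with an shRNA against XRN2. Total RNA was column-purified, libraries were made with the forward QuantSeq 3' kit and run on an Illumina HiSeq instrument, per the labels' protocols. The deposited values are raw counts of reads per gene symbol, 1 column per library. Reads were processed with STAR 2.5, HTSeq 0.7 and DESeq2 on the hg19 build, per the submitters' processing notes, which do not say what each tool was used for. The annotation release and the strand setting of the counting are not given in the sources used here, so genes that overlap or lie antisense to each other cannot be separated with certainty. Groups and replicate numbers were taken from the sample titles.

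Each deposited table of counts held 56638 gene entries and 5 closing entries that name no gene, which were left out of library sizes and tests. Uniquely aligned reads outside any gene made up 11.0% to 12.4% of all entries, reads shared by overlapping genes 0.875% to 0.92%, and reads with several alignments 37.6% to 39.7%. Gene counts per library ran from 27971400 to 33744900. No pair of libraries was alike enough to be one library deposited again: the chi-square per degree of freedom between libraries was at least 19.6.

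Counts were filtered with filterByExpr by group (minimum count 10), which kept 15918 genes, and scaled by the trimmed mean of M values. All 6 libraries entered one model of group means with 3 residual degrees of freedom, fitted with the robust quasi-likelihood method of edgeR 4.0.16 in R 4.3.3 (common dispersion 0.0237, median prior degrees of freedom 9.55). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Standard errors are the log2 fold change divided by the square root of the F statistic. CPM values use the scaled library sizes. With 2 libraries per group, both of one group lie on one side of both of the other for 33.3% of unchanged genes.

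The comparisons, the alternatives, the gene lists and the rule for named genes were fixed before the data were examined. The rule named the targets, TARBP2, APP and ZNF395; up to 12 genes per direction (6 between the knockdowns) past the threshold with a symbol, a mean log2 CPM of at least 3 and both libraries of one group above both of the other; and the 4 members with the smallest p of each list described. Of 34 lists, 33 had at least 5 tested members and were tested with camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2), adjusted over the lists. Member counts are given over all genes and adjusted over the list alone.

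Alternatives were DESeq2 1.42.0, limma-voom, other scalings, other filters on low counts, fits of the compared groups only, a replicate block, a fit without the robust option, camera with an estimated correlation, fry, and omission of each library. Added after the data were seen were DESeq2 without independent filtering, a correction for GC content, and a test restricted to genes whose 3' UTR lacks certain short sequences. Fold changes of both knockdowns were set beside 50 simulations of unchanged groups. In these all libraries, controls included, were drawn around the control means, and both comparisons shared the simulated controls.

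Gene biotypes, neighbours, transcript GC content and 3' UTR sequences came from the GENCODE 29 annotation of GRCh38, matched by symbol for 13286 genes and by another symbol for 608, 87.3% of those tested. Because the reads were aligned to another build, no coordinates are given. Deviations of each library were scanned for 16157 sequences of 7 bases in the 3' UTRs of 9860 genes with Python 3.11.15. The deviations and the presence of each sequence were first regressed on mean log2 CPM and on the length and base shares of the 3' UTR.

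The gene test was run on simulated counts of 15918 genes with 50 changed at each of 4 sizes. The changed genes were drawn from those with a log2 CPM above 3. For EXOSC10 knockdown against control it recovered 36% of genes changed 1.5-fold, 88% changed 2-fold and 100% changed 3-fold or 4-fold, with 14 false calls. For XRN2 knockdown against control it recovered 16%, 90% and 100%, with 19 false calls. So many changed genes make the adjusted threshold easier to reach, so these shares need not hold for a comparison with few calls. Camera on simulated XRN2 libraries, with 40 lists in all, found 4 of 10 lists shifted 1.1-fold and 10 of 10 shifted 1.3-fold. It made 0 false calls among the lists not shifted. Genes were drawn independently there, so this does not test the preset correlation. The sequence scan ranked the planted sequence first in 10 of 10 trials at a shift of -0.08 and at -0.2.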

Results

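RNA abundance was measured in MDA-LM2 cells, a derivative of the MDA-MB-231 breast cancer line selected for spread to the lung. The cells carried a short hairpin RNA (shRNA) against EXOSC10, an shRNA against XRN2, or a control shRNA. EXOSC10 is a catalytic subunit of the nuclear RNA exosome and degrades RNA from its 3' end. XRN2 is the nuclear exonuclease that degrades RNA from its 5' end and acts in transcription termination. The libraries were made with a kit that counts reads near the 3' end of polyadenylated RNA. Each of the 3 groups held 2 libraries, labelled biological replicates; whether they came from separate infections is not given in the sources used here, so p-values measure the spread between these libraries. Reads assigned to genes numbered 33744900 and 31277500 in the control libraries, 28165200 and 33492100 in the EXOSC10 knockdown libraries and 30498600 and 27971400 in the XRN2 knockdown libraries. The correlation of log2 CPM (counts per gene scaled by library size) between libraries lay between 0.977 and 0.989, across genes that are not independent replicates. Control replicate 2 had r = 0.988 and 0.989 with EXOSC10 knockdown replicates 1 and 2, and r = 0.989 with control replicate 1. The EXOSC10 knockdown libraries had r = 0.986 with each other, below the r of each with control replicate 2. The XRN2 knockdown libraries had r = 0.985 with each other. Across 8929 genes with a known GC content, the deviation of a library from the gene means followed transcript GC content with Spearman's rho = 0.427 in control replicate 1 and -0.372 in XRN2 knockdown replicate 1. In the other libraries rho lay between -0.193 and 0.101. Genes are not independent replicates in these correlations either.

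The targeted genes were examined first. XRN2 mRNA stood at 226 and 213 CPM in the control libraries and at 63.1 and 37.1 CPM in the XRN2 knockdown libraries, 77.2% lower (log2 fold change -2.13, SE 0.23, n = 2 per group; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00625). EXOSC10 mRNA stood at 91.6 and 86.4 CPM in the control libraries and at 57.1 and 30.1 CPM in the EXOSC10 knockdown libraries (log2 fold change -1.03, SE 0.25, n = 2 per group). The EXOSC10 difference did not pass the threshold over all genes (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.557; unadjusted p = 0.00202). DESeq2 gave an adjusted p of 0.0157 for it, within a range of 2.67e-06 to 1.00 over all alternatives tried with edgeR, DESeq2 and limma. Without EXOSC10 knockdown replicate 1 the log2 fold change was -1.56 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00293), and without replicate 2 it was -0.64. Without control replicate 1 the XRN2 difference was -2.10 and no longer passed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.224, the highest of its alternatives). Each remaining lone library is assumed to vary like the other groups. In the group not aimed at them, EXOSC10 had a log2 fold change of -0.28 (SE 0.24) in XRN2 knockdown and XRN2 one of -0.20 (SE 0.22) in EXOSC10 knockdown; neither passed. The latter was -0.37 and -0.05 without EXOSC10 knockdown replicate 1 and 2.

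**Figure D1:**
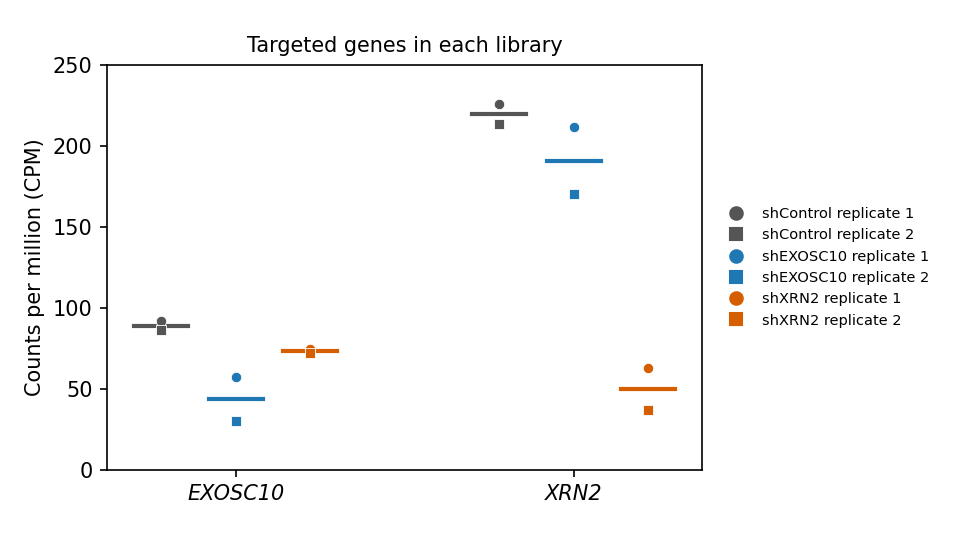
EXOSC10 and XRN2 mRNA in CPM in each of the 6 libraries, by group; points are libraries and horizontal bars are group means. XRN2 lies at 63.1 and 37.1 CPM in XRN2 knockdown against 226 and 213 CPM in control, and EXOSC10 at 57.1 and 30.1 CPM in EXOSC10 knockdown against 91.6 and 86.4 CPM in control.

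Depletion of EXOSC10 was compared with the control shRNA to ask which polyadenylated RNAs change when this exosome nuclease is reduced. TULP3, an adapter that carries receptors into the primary cilium, rose 2.51-fold, from 19.3 and 21.6 CPM to 46.0 and 56.3 CPM (log2 fold change 1.33, SE 0.16, n = 2 per group; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0299). It was the single gene of 15918 tested that passed the threshold. An unadjusted p under 0.05 was reached by 1106 genes, 616 higher and 490 lower, where chance alone gives 796. The share of these genes that were higher was 55.7%, and 68.6% when libraries were scaled by their totals only. The excess over chance was absent in the fit without control replicate 1, which leaves 1 control library. Both knockdown libraries lay on one side of both control libraries for 37.4% of genes, where chance gives 33.3%. The annotated 3' untranslated region (UTR) of TULP3 holds 5 copies of AAGAGCA, a sequence found by a scan added after the data were seen. Its 1605 carriers lay on average 0.037 (log2, SE 0.007) higher than other genes in EXOSC10 knockdown and 0.021 (SE 0.009, z = 2.25) higher in XRN2 knockdown. DESeq2 called 16 genes higher and 13 lower, and limma-voom called 0 (1148 at an unadjusted p under 0.05). The count was 5 and 6 without EXOSC10 knockdown replicate 1 and 2, and 2 without either XRN2 knockdown library. Without control replicate 1 or 2 the TULP3 log2 fold change was 1.24 and 1.41 and did not pass (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.633 and 0.330; range over all alternatives 1.92e-10 to 0.633).

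Among the gene lists, targets of ATF4, the transcription factor of the integrated stress response, lay lower in EXOSC10 knockdown, with a median log2 fold change of -0.39 over 32 members. Adjusted over the list alone, 13 of them fell, while over all genes tested no member passed. Those 13 included JDP2, a bZIP repressor (-0.99, SE 0.16), CHAC1, a glutathione-degrading enzyme (-0.67, SE 0.16), PCK2, a mitochondrial gluconeogenic enzyme (-0.66, SE 0.17), and NUPR1, a stress-response regulator (-0.91, SE 0.23). Markers of luminal epithelium had a median of -0.31 over 17 members; the keratins KRT19 (-0.60, SE 0.14) and KRT18 (-0.58, SE 0.14) fell adjusted over the list alone. Camera, which compares a list with all other genes, called 8 of 33 lists, 2 higher and 6 lower (Benjamini-Hochberg adjusted p = 3.6e-06 for the ATF4 targets and 0.00493 for the luminal markers). No camera call in any of the 3 comparisons held with an estimated correlation; the smallest here was adjusted p = 0.495 with an estimated correlation, for both of these lists, and fry called 0 of the 33. The other lists called lower were histones (median -0.25, adjusted p = 0.00751), ribosomal proteins (-0.14, 0.0086), RNAs encoded by the mitochondrial genome (-0.17, 0.00977; 15 of 15 members negative) and the respiratory chain (-0.11, 0.0248). No single member of these 4 lists passed, HIST4H4 (-1.41), RPL26 (-0.48), MT-ATP6 (-0.28) and COX7C (0.58, against the direction of the respiratory chain) included. Nuclear long noncoding RNAs (median 0.18, adjusted p = 0.0262) and zinc finger genes (0.09, 0.00808) were called higher. For these 6 lists camera gave adjusted p = 0.891 with an estimated correlation. RPPH1, the RNA component of RNase P, rose by 0.92 (log2, SE 0.19) adjusted over the list alone. Since the kit counts polyadenylated RNA, reads of RPPH1 need not measure the whole amount of this RNA.

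The EXOSC10 list calls depended on single libraries. Without control replicate 2 camera called 3 lists instead of 8; the luminal markers, ribosomal proteins, respiratory chain, zinc finger genes and nuclear noncoding RNAs were lost (camera, Benjamini-Hochberg adjusted p = 0.058, 0.124, 0.162, 0.0602 and 0.162). Without EXOSC10 knockdown replicate 1 the same lists other than the ribosomal proteins were lost (camera, Benjamini-Hochberg adjusted p between 0.130 and 0.508, the latter for the noncoding RNAs). Without EXOSC10 knockdown replicate 2 the histones, ribosomal proteins and mitochondrially encoded RNAs were lost (camera, Benjamini-Hochberg adjusted p = 0.0854, 0.659 and 0.474), and the last of these also without control replicate 1 (0.255). The ATF4 targets kept their call without any 1 library, with medians between -0.44 and -0.29. Without EXOSC10 knockdown replicate 2 the luminal median was -0.55 and NUPR1 had a value of -1.38; without replicate 1 NUPR1 had -0.56, and the mitochondrially encoded, ribosomal protein and histone medians were -0.32, -0.27 and -0.40. The ribosomal protein and mitochondrially encoded medians shrank to -0.07 each without replicate 2, and the latter was -0.10 without control replicate 1. With 1 library left out RPL26 ran from -0.75 to -0.25 and MT-ATP6 from -0.43 to -0.11. The median of the nuclear noncoding RNAs ran from 0.09 to 0.26 in the same way. That of the zinc finger genes ran from 0.06 to 0.12 and that of the histones from -0.40 to -0.18. Without control replicate 1, 1 of the ATF4 targets rather than 13 was lower adjusted over the list alone. Histone and ribosomal protein genes have near-identical copies that share reads, and their values are uncertain. As the kit counts polyadenylated RNA, reads of histone genes need not measure the whole amount of their RNAs. Over genes, the EXOSC10 fold changes followed transcript GC content with rho = -0.287.

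Depletion of XRN2 was compared with the control shRNA in the same way, and 23 genes passed the threshold, 11 higher and 12 lower. EREG, the EGF receptor ligand epiregulin, rose 2.99-fold, from 39.3 and 47.8 CPM to 155 and 106 CPM (log2 fold change 1.58, SE 0.18, n = 2 per group; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00625). STC1, a secreted glycoprotein hormone, rose 1.92-fold, from 177 and 180 CPM to 355 and 329 CPM (log2 fold change 0.94, SE 0.15). CDK6, a cyclin-dependent kinase of the G1 phase, rose by 1.14 on the log2 scale (SE 0.16) and TULP3 by 1.36 (SE 0.16). CDK6 stood at 141 and 114 CPM in XRN2 knockdown, 122 and 119 CPM in EXOSC10 knockdown and 50.9 and 65.2 CPM in control. The lysosomal arylsulfatase gene ARSB (1.69, SE 0.27) and TMEM251, needed to sort lysosomal enzymes (1.36, SE 0.21), also rose. JDP2 had the smallest p of all genes and stood at 61.3 and 50.8 CPM in control against 17.9 and 16.1 CPM in knockdown (log2 fold change -1.72, SE 0.16; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00193).

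CHAC1 (log2 fold change -1.26, SE 0.16), the asparagine synthetase ASNS (-1.04, SE 0.18) and PHGDH, the first enzyme of serine synthesis (-0.995, SE 0.15), fell in XRN2 knockdown beside JDP2. The histone H4 gene HIST1H4C (-1.22, SE 0.18), the kinase gene RPS6KA2 (-1.22, SE 0.17), the Hippo pathway transcription factor TEAD2 (-1.06, SE 0.18) and the myosin light chain gene MYL9 (-0.85, SE 0.15) also fell. So did HYI (-1.07), FAM207A (-1.04) and the locus MIR663A (-1.25, SE 0.16). The kit counts polyadenylated RNA, so reads of MIR663A need not measure the mature microRNA. Reads of HIST1H4C need not measure the whole amount of its RNA for the same reason. The zinc finger gene ZNF146 (1.24, SE 0.19), CCDC90B (1.02), the splicing factor subunit SF3B14 (1.00, SE 0.17) and the noncoding RNA LINC00324 (0.92, SE 0.15) rose. The remaining call was RP11-284F21.9 (2.25, SE 0.29), a clone-named gene outside the naming rule and named after its values were seen. Of the 23 genes, XRN2, MIR663A and RP11-284F21.9 alone also passed in the direct test between the knockdowns. An unadjusted p under 0.05 was reached by 2763 genes, 1499 higher and 1264 lower, where chance gives 796; both knockdown libraries lay on one side of both control libraries for 51.2% of genes, where chance gives 33.3%.

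Every one of the 23 genes kept its direction when any 1 of the 6 libraries was left out. Both knockdown libraries lay on one side of both control libraries for each of these genes, so this was nearly fixed beforehand. The calls depended on the libraries. Without control replicate 1, JDP2 alone passed (log2 fold change -1.59; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.047, the highest of its alternatives), and the other 22 genes reached adjusted p values of up to 0.604. Without XRN2 knockdown replicate 1, 6 of the 23 still passed (EREG, JDP2, MIR663A, RP11-284F21.9, TULP3 and XRN2), and without replicate 2, 13 did. The total was 244 without control replicate 2, 224 and 311 without EXOSC10 knockdown replicates 1 and 2, and 44 without XRN2 knockdown replicate 2. DESeq2 called 327 genes higher and 187 lower, all 23 among them. XRN2 fold changes followed transcript GC content with rho = -0.382, and after a correction for that trend 14 of the 22 genes with a known GC content passed. All 22 kept their direction, with a fold change on the log2 scale of at least 0.704 of the uncorrected one and adjusted p values of at most 0.066 (edgeR quasi-likelihood test, Benjamini-Hochberg).

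**Figure D2:**
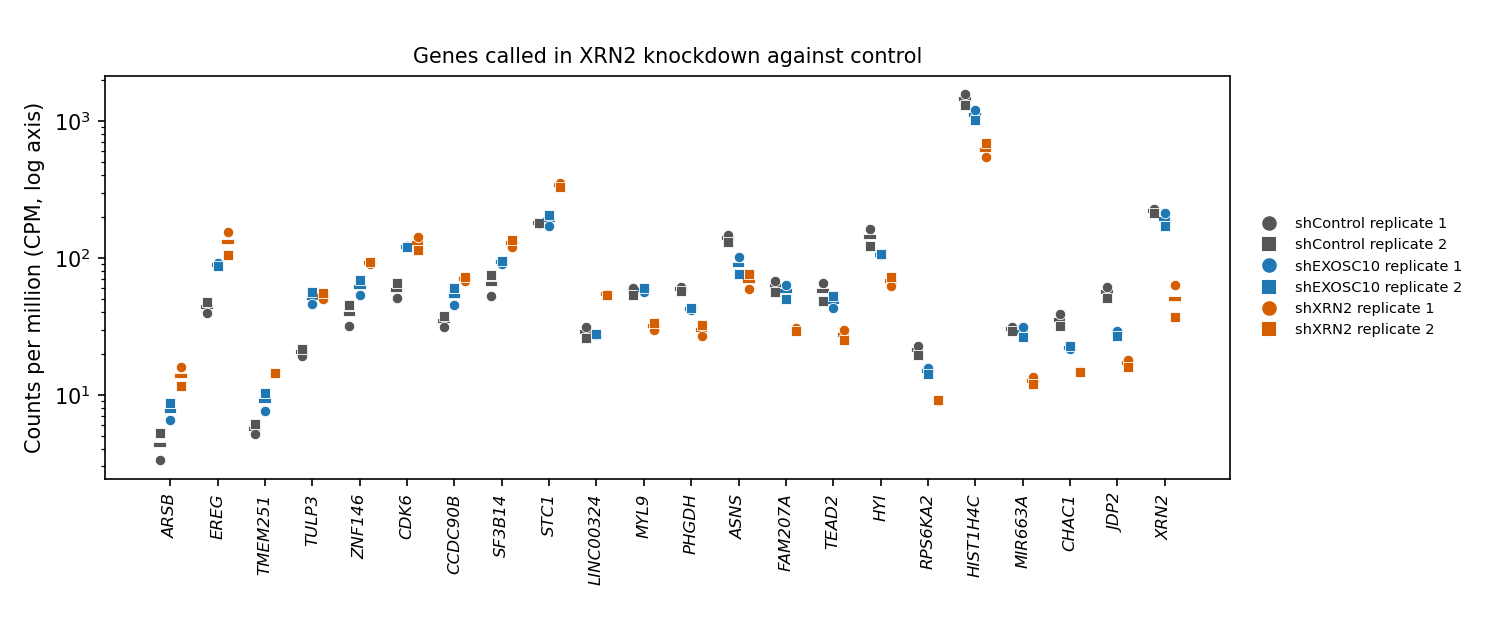
CPM on a logarithmic axis in each of the 6 libraries for the 22 genes named by the rule among the 23 called in XRN2 knockdown, ordered by log2 fold change in XRN2 knockdown against control. Circles and squares are replicates 1 and 2, and horizontal bars are group means; JDP2 lies at 61.3 and 50.8 CPM in control, 29.4 and 26.9 CPM in EXOSC10 knockdown and 17.9 and 16.1 CPM in XRN2 knockdown.

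The ATF4 targets formed the list with the smallest p in XRN2 knockdown, with a median log2 fold change of -0.48 over 32 members. JDP2, CHAC1, PHGDH and ASNS fell over all genes tested; adjusted over the list alone, 17 members fell, ATF4 itself among them (-0.72, SE 0.19). ATF3 (0.95, SE 0.33), CEBPB (0.48, SE 0.18) and the cystine transporter gene SLC7A11 (0.43, SE 0.16) rose on that basis, against the direction of the list. Without control replicate 1, 9 members rather than 17 were lower adjusted over the list alone, and without XRN2 knockdown replicate 1, 11 were. Camera called this list lower (Benjamini-Hochberg adjusted p = 1.47e-07; adjusted p = 0.525 with an estimated correlation), and fry, which asks whether the members move one way on balance, gave an adjusted p of 0.0358. NF-kB and inflammatory genes had a median of 0.83 over 23 members, and the cytokines CSF3 (0.98, SE 0.20) and LIF (2.49, SE 0.55) rose adjusted over the list alone. Interleukin genes IL6 (2.69, SE 0.76) and IL1A (1.11, SE 0.36) did not pass; without XRN2 knockdown replicate 1 their values were 1.06 and 0.43, and that of CSF3 0.64. Camera called the list higher (Benjamini-Hochberg adjusted p = 0.000235; adjusted p = 0.961 with an estimated correlation). Without XRN2 knockdown replicate 2, 14 members of it were higher adjusted over the list alone. Its median deviation was 0.82 in XRN2 knockdown replicate 1 and -0.02 in replicate 2; without replicate 1 the list median was 0.24 and the call was lost (camera, Benjamini-Hochberg adjusted p = 0.163).

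Host genes of small nucleolar RNAs had a median of 0.19 over 29 members in XRN2 knockdown, and 10 rose adjusted over the list alone, among them DANCR (0.87, SE 0.17), SNHG3 (0.73, SE 0.15), ZFAS1 (0.85, SE 0.19) and SNHG7 (0.75, SE 0.18). Mitochondrial ribosomal protein genes had a median of 0.09 over 75 members; 12 rose and 1 fell adjusted over the list alone, led by MRPL33 (1.03, SE 0.18) and MRPS14 (0.82, SE 0.15). Immediate early genes had a median of 0.19 over 27 members, and DUSP5 (0.74, SE 0.19) and CYR61 (0.81, SE 0.22) rose adjusted over the list alone. The mitochondrial ribosomal median was 0.14 without control replicate 1, and 0.18 and 0.04 without XRN2 knockdown replicate 1 and 2. CYR61 had a value of 0.48, ZFAS1 0.57 and SNHG7 0.48 without control replicate 1, and without control replicate 2 CYR61 had 1.23. The immediate early median was 0.08 and 0.43 without XRN2 knockdown replicate 1 and 2, and 0.33 without control replicate 2. Histone genes had a median of -0.33 over 31 members, which ran from -0.41 to -0.21 with 1 library left out. HIST1H4C, HIST1H1E (-0.89, SE 0.19) and HIST1H3A (-1.35, SE 0.37) fell adjusted over the list alone, and only HIST1H4C of these over all genes. Camera called these 4 lists (Benjamini-Hochberg adjusted p = 0.00264, 0.0269, 0.0139 and 0.0139; adjusted p = 0.961 with an estimated correlation for each). The snoRNA hosts were lost without XRN2 knockdown replicate 2 (camera, adjusted p = 0.105), the immediate early genes without control replicate 1 (0.0572) or XRN2 knockdown replicate 1 (0.310), and the histones without XRN2 knockdown replicate 2 (0.311) or after the GC correction (0.0596). The mitochondrial ribosomal genes were lost without control replicate 2 (0.156), XRN2 knockdown replicate 2 (0.311) or either EXOSC10 knockdown library (camera, adjusted p = 0.0537 and 0.0531). No snoRNA host or mitochondrial ribosomal gene was higher adjusted over the list alone without control replicate 1, and 0 and 4 of them were without XRN2 knockdown replicate 2. With a filter at 5 CPM the histone median was 0.24 in XRN2 knockdown and 0.14 in EXOSC10 knockdown, while camera's direction was lower in both and neither passed (camera, adjusted p = 0.493 and 0.902).

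**Figure D3:**
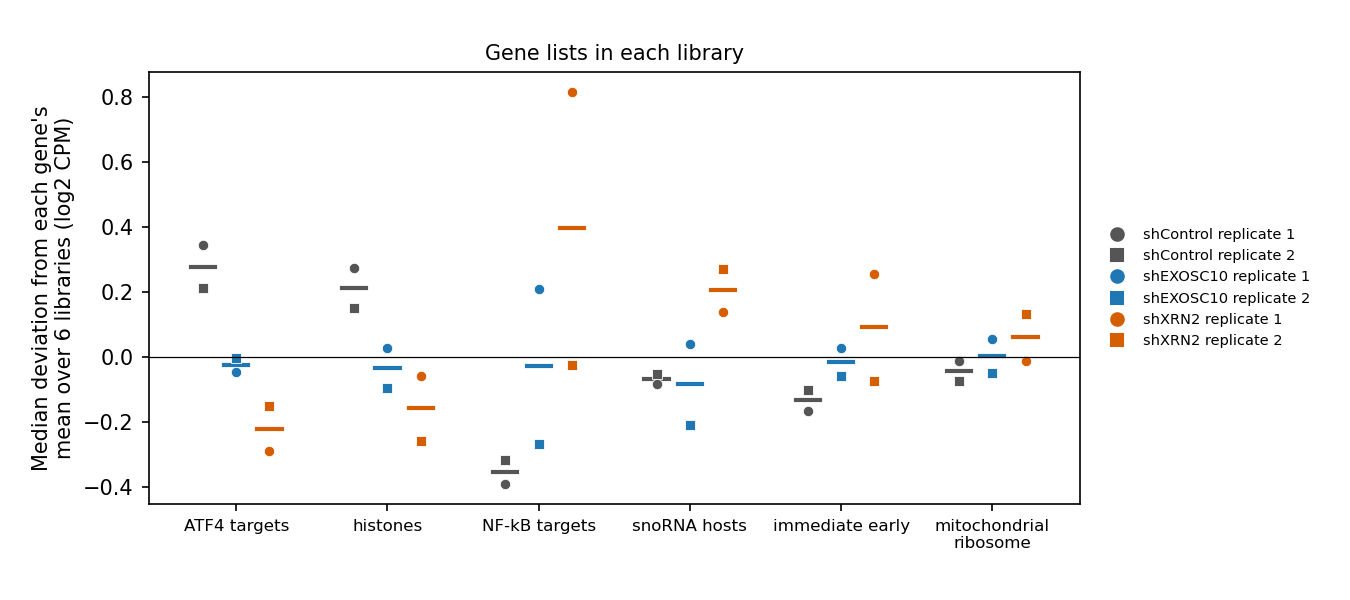
Median deviation of the 6 gene lists called in XRN2 knockdown from the gene means over all libraries (log2 CPM), in each of the 6 libraries; points are libraries and horizontal bars are group means. The ATF4 targets lie at 0.34 and 0.21 in control against -0.29 and -0.15 in XRN2 knockdown, and the NF-kB genes at 0.82 and -0.02 in the XRN2 knockdown libraries. Under other scalings the median of the snoRNA hosts in EXOSC10 knockdown against control turned from 0.00504 to -0.00838, and that of the histones between the knockdowns from -0.0140 to 2.59e-05; no median of a called list changed sign.

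The knockdowns were then compared directly, since a call in 1 comparison and not in the other does not show a difference. XRN2 (log2 fold change of EXOSC10 knockdown over XRN2 knockdown 1.93, SE 0.23) and MIR663A (1.19, SE 0.16) were higher in EXOSC10 knockdown. RNY5, a Y RNA (-1.87, SE 0.27), VTRNA2-1, a vault-like RNA (-2.71, SE 0.36), and the clone-named genes RP11-284F21.9 (-2.56, SE 0.30) and RP11-284F21.10 (-1.88, SE 0.25) were lower in EXOSC10 knockdown. RNY5 stood at 13.5 and 8.45 CPM in XRN2 knockdown, 3.09 and 2.92 CPM in EXOSC10 knockdown and 4.99 and 3.75 CPM in control. These 4 lie outside the naming rule and were named after their values were seen. VTRNA2-1 was weakly expressed, at 0.461 and 0.729 CPM in EXOSC10 knockdown and 3.79 and 4.15 CPM in XRN2 knockdown. The kit counts polyadenylated RNA, so reads of RNY5 and VTRNA2-1 need not measure the whole amount of these RNAs. The 6 genes passed the edgeR quasi-likelihood test with n = 2 per group (Benjamini-Hochberg adjusted p between 0.019 and 0.0385); 1273 genes had an unadjusted p under 0.05. Without control replicate 1 or 2, which enter through the shared estimate of the spread, RP11-284F21.9 alone passed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0182 and 0.0209), and the other 5 reached at most 0.0629 and 0.0677. RP11-284F21.9 also passed without each knockdown library in turn. XRN2 was lost without EXOSC10 knockdown replicate 1, MIR663A without that library or either XRN2 knockdown library, VTRNA2-1 without it or XRN2 knockdown replicate 2, RP11-284F21.10 without EXOSC10 or XRN2 knockdown replicate 2, and RNY5 without any library other than XRN2 knockdown replicate 2 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p up to 0.113). Over all alternatives the adjusted p of RP11-284F21.9 lay between 5.19e-16 and 0.0627. DESeq2 called 17 genes higher and 19 lower, and limma-voom 1 and 1.

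Host genes of snoRNAs were lower in EXOSC10 knockdown than in XRN2 knockdown, with a median log2 fold change of -0.26 over 29 members. ZFAS1 (-1.02, SE 0.19), SNHG15 (-0.64, SE 0.18), GAS5 (-0.52, SE 0.15) and TAF1D (-0.52, SE 0.15) fell adjusted over the list alone. Ribosomal protein genes had a median of -0.20 over 84 members and NF-kB genes one of -0.44 over 23, and no member of either list passed, RPL21 (-1.10) and CCL20 (-2.90; -0.90 without XRN2 knockdown replicate 1) included. ATF4 targets had a median of 0.18 over 32 members, of which JDP2 (0.73, SE 0.16) was higher adjusted over the list alone, and genes of the G1/S transition and replication one of 0.13 over 46. Camera called these 5 lists (Benjamini-Hochberg adjusted p = 9.49e-05, 9.49e-05, 0.00618, 0.00618 and 0.0198; adjusted p = 0.872 with an estimated correlation for each). Without EXOSC10 knockdown replicate 2 camera called 0 of the lists, and the smallest of these adjusted p values among the 5 was 0.0632, for G1/S. Without XRN2 knockdown replicate 1 the NF-kB median was 0.07, the opposite direction, and the ATF4 (0.0886) and G1/S (0.798) calls were lost; without replicate 2 the ribosomal protein (0.784) and snoRNA host (camera, adjusted p = 0.0765) calls were lost. With 1 library left out the ribosomal protein median ran from -0.36, without XRN2 knockdown replicate 1, to -0.03, without replicate 2. The G1/S median ran from 0.0058 to 0.19 and the ATF4 median from 0.08 to 0.23, each lowest without XRN2 knockdown replicate 1. The snoRNA host median ran from -0.43 to -0.16 with 1 library left out. Without EXOSC10 knockdown replicate 1 the snoRNA host and NF-kB medians were -0.42 and -0.76, and 11 lists were called. G1/S was also lost without EXOSC10 knockdown replicate 1 (camera, adjusted p = 0.0859).

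TULP3 was the single gene called in both knockdowns, higher in each. The comparisons share both control libraries. In 50 simulations of unchanged groups, with simulated controls shared by both comparisons, up to 2 genes were called in both. So 1 shared gene lies within the range of these simulations, whose highest count does not say how often it arises. The level of TULP3 in the knockdowns did not differ by more than their spread (log2 fold change -0.03, SE 0.16). TULP3 was called in both by DESeq2, which called 15 genes in both, and not by limma-voom. Across 15918 genes the fold changes of the knockdowns had a correlation of 0.582, against a median of 0.496 and a highest value of 0.514 in these simulations. The covariance was 0.117 against 0.0693 in the simulations, a difference of 0.048. The sign was shared by 73.7% of genes, against 66.7%. Genes were drawn independently in the simulations, so trends across many genes of a library, as with GC content, are absent from the simulated values. The 2 controls cannot be split into separate sets with replicates, so part of the excess may come from the shared controls.

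TARBP2, an RNA-binding protein reported to destabilise APP and ZNF395 mRNAs in metastatic breast cancer cells, and these transcripts were examined by name. TARBP2 had a log2 fold change of -0.38 (SE 0.15) in EXOSC10 knockdown and -0.27 (SE 0.15) in XRN2 knockdown. APP, the amyloid precursor protein gene, had values of 0.01 and -0.01 (SE 0.14 each), and ZNF395, a zinc finger gene, values of 0.45 and 0.49 (SE 0.21 each). With 1 library left out TARBP2 ran from -0.41 to -0.14 in XRN2 knockdown, lowest and highest without XRN2 knockdown replicate 2 and 1. ZNF395 ran from 0.09, without EXOSC10 knockdown replicate 2, to 0.74 in EXOSC10 knockdown and from 0.29, without control replicate 1, to 0.72 in XRN2 knockdown. None of the 3 passed in any comparison (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p between 0.263 and 0.990), adjusted over the list alone either.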

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

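The direct tests between the knockdowns were planned; the shares of reads outside genes were not tested. The knockdowns differed in the test of the difference itself for XRN2 (log2 fold change of EXOSC10 over XRN2 knockdown 1.93), MIR663A (1.19), RNY5 (-1.87), RP11-284F21.10 (-1.88), RP11-284F21.9 (-2.56) and VTRNA2-1 (-2.71). VTRNA2-1 stood at 3.79 and 4.15 CPM in XRN2 knockdown, 0.461 and 0.729 CPM in EXOSC10 knockdown and 1.18 and 0.889 CPM in control. By camera the knockdowns differed for ATF4 targets (median 0.18), G1/S genes (0.13), NF-kB genes (-0.44), ribosomal protein genes (-0.20) and snoRNA host genes (-0.26), none of them with an estimated correlation (smallest adjusted p = 0.872 with an estimated correlation).

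Reads outside annotated genes were not part of any comparison. As a share of uniquely aligned reads they were 19.2% and 19.6% in XRN2 knockdown against 18.6% and 19.1% in control, a difference of group means of 0.538 percentage points. In EXOSC10 knockdown they were 20.4% and 17.9%, on both sides of the control values.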

How the results depend on the processing

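Added after the data were seen were DESeq2 without independent filtering, the GC correction with its uncorrected partner, and the test on genes without the sequences AAGAGCA, GAAGAGC, CTGCTA and CCGAAC; all else was planned. The numbers of genes called for EXOSC10 knockdown against control, XRN2 knockdown against control and EXOSC10 knockdown against XRN2 knockdown were 1, 23 and 6. They became 29, 514 and 36 with DESeq2, 13, 456 and 34 with DESeq2 without independent filtering, and 117, 941 and 136 with no low-count filter, where the prior degrees of freedom became infinite and every gene was given nearly the same spread. With library totals only they were 0, 10 and 0; with the compared groups only 2, 152 and 1. Limma-voom called 0 for EXOSC10 and 2 between the knockdowns, the fit without robust 0 for EXOSC10, and upper-quartile factors 37 for XRN2. The GC correction left 15 for XRN2 and 2 between the knockdowns, where its uncorrected partner left 3; genes without the sequences gave 0 for EXOSC10 and 0 between the knockdowns, with 7154 genes tested. At an unadjusted p under 0.05 EXOSC10 knockdown had 1148 genes with limma-voom, and 1106 in the planned edgeR quasi-likelihood test. With 1 library left out the 3 counts ran from 0 to 6, 1 to 311 and 1 to 9. Whether the replicate numbers shared between groups pair the samples stays open. The correlations of same-numbered deviations were 0.165, -0.007 and 0.0111, and no label gives the numbers a meaning. With the replicate block 416 genes were called for XRN2 and the other counts did not change by over 1.5 times. EXOSC10 in its own knockdown passed with DESeq2 (-1.03, adjusted p = 0.0157), DESeq2 without independent filtering (-1.03, 0.0274) and no low-count filter (-1.02, 2.67e-06), and ran from -1.56 to -0.64 with 1 library left out; XRN2 in its own ran from -2.57 to -1.80. Genes called in both knockdowns, 1 in the planned fit, numbered 15 with DESeq2, 10 without its independent filtering, 68 with no low-count filter, and 0 with limma-voom, library totals only, the fit without robust, genes without the sequences (which leave out TULP3) and an adjusted p threshold of 0.01; with 1 library left out they ran from 0 to 3. Lists called numbered 8, 6 and 5; they became 0, 0 and 0 with an estimated correlation and 0, 1 and 0 with fry. With the 5 CPM filter they became 10 for XRN2 and 8 between the knockdowns, and with the GC correction 8 between the knockdowns. With 1 library left out they ran from 3 to 11, 5 to 8 and 0 to 11.

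Direction turned for APP, TARBP2 and ZNF395, none of them called, and for 2 lists that were called. APP became -0.00169 with upper-quartile factors and -0.0175 with the GC correction in EXOSC10 knockdown. In XRN2 knockdown it became 0.0327 with library totals only, 0.00934 with the 5 CPM filter, 0.00674 with the compared groups only and 0.00424 in genes with a known GC content. With 1 library left out APP ran from -0.0386 to 0.0645, -0.0576 to 0.0491 and -0.0331 to 0.0707 in the 3 comparisons, and between the knockdowns TARBP2 ran from -0.24 to 0.0350, and ZNF395 from -0.40 to 0.25. The NF-kB list between the knockdowns, at -0.44 with all libraries, ran from -0.997 to 0.0747, the latter without XRN2 knockdown replicate 1. The histone list turned from -0.25 to 0.14 in EXOSC10 and from -0.33 to 0.24 in XRN2 knockdown with the 5 CPM filter, which drops weakly expressed members. Of the other values of named genes under settings other than an omitted library, 1326 kept direction and side of the threshold, 96 newly passed and 55 no longer passed. Apart from the filter's spread estimate and the smaller gene sets, the cause was not tested.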

Other observations

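The scans of 3' UTR sequences and the comparison of neighbouring genes were added after the gene results were seen, and the tests of ACCGAAC in the XRN2 mRNA and of separate GAAGAGC or AAGAGCA sites were chosen only after a result was seen. Heat shock genes HSPA1A (log2 fold change 0.89, SE 0.21) in EXOSC10 knockdown, and HSPA1A (2.01-fold) and the co-chaperone gene BAG3 (log2 fold change 1.33, SE 0.25) in XRN2 knockdown, rose adjusted over the list alone. The microRNA host genes MIR17HG (1.36, SE 0.25) and MIR22HG (0.81, SE 0.19) rose in XRN2 knockdown on the same basis, and both were lower in EXOSC10 than in XRN2 knockdown (-0.98 and -0.66). The exosome cofactor genes RBM7 (0.71, SE 0.19) and WDR61 (0.75, SE 0.20) rose in XRN2 knockdown adjusted over the list alone. Of 57 small nucleolar and Cajal body RNA genes tested, 5 fell there on that basis, among them SCARNA22 (-0.90, SE 0.17), SNORA79 (-0.94, SE 0.19) and SNORA12 (-0.94, SE 0.20); such genes lie inside host genes, and their reads are uncertain. Among p53 targets CCNG1 (0.75, SE 0.19) rose, while SESN2 (-0.77, SE 0.15), also an ATF4 target, and PHLDA3 (-0.60, SE 0.19) fell. In the lung metastasis signature EREG rose in EXOSC10 knockdown too, adjusted over the list alone (1.04, SE 0.18). None of these lists was called by camera.

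Antisense and long intergenic noncoding RNA genes had median log2 fold changes of 0.11 (219 genes) and 0.10 (172 genes) in XRN2 knockdown, against -0.01 for 12045 protein-coding genes. In EXOSC10 knockdown the medians were 0.05, 0.06 and 0.00477. No test was run between these classes. Camera did not call the lists of genes named as antisense or as long intergenic noncoding RNAs in XRN2 knockdown (Benjamini-Hochberg adjusted p = 0.313 and 0.102; adjusted p = 0.961 with an estimated correlation for each).

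Genes with the sequence CCTGCTA in the 3' UTR lay lower in EXOSC10 knockdown replicate 2 alone: 976 genes shifted by -0.074 (log2, SE 0.008; z = -9.03), against z = 1.12 in replicate 1, and 92 genes with ACCGAAC shifted by -0.202 (SE 0.032; z = -6.23) in XRN2 knockdown replicate 2, against z = 0.94 in replicate 1. Each was the lowest of 16157 sequences in its library, with a permutation p corrected for all of them of 0.000999, the smallest that 1000 permutations can give. The reverse complements, of equal GC content, had z = 1.23 and z = 0.53. All z values were taken after regression on the base shares and length of the 3' UTR and on mean log2 CPM. Fitted trends with base shares were thus removed beforehand, and the reverse complements say little about GC content. A trend of another form is not excluded. A microRNA of the miR-15/16 family is argued against for CCTGCTA, since its site had z = -2.21. A candidate explanation is repression by the guide strand of a hairpin carried by 1 replicate of each group and not by the other. Genes with 2 or more CTGCTA matches lay lower than genes with 1 by -0.032 (SE 0.009, permutation p = 0.00028). CTGCTA is shared by the lowest sequences of that same library, so this difference is not independent support. The XRN2 mRNA contains ACCGAAC, as do 3.88% of mRNAs of similar length. The EXOSC10 mRNA contains CCTGCTA, as do 15.3% of mRNAs of similar length. The hairpin sequences are not given in the sources used here, so whether the replicates carry different hairpins stays open.

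The 1262 genes with GAAGAGC in the 3' UTR lay higher in EXOSC10 knockdown than in control. Their shift was 0.042 (SE 0.007, z = 5.79, permutation p corrected for all sequences 0.000999, the smallest possible). They did not pass in XRN2 knockdown (z = 2.92) or in the mean of both comparisons (z = 4.54, permutation p corrected for all sequences 0.0649). Each library was also set against the mean of the libraries of the other groups. The control libraries then had z = -3.31 and -5.68, which restates the knockdown comparisons. The EXOSC10 knockdown libraries had z = 4.38 and 3.78, and the XRN2 knockdown libraries z = 1.46 and 0.35. In the mean of both comparisons the reverse complement, of equal GC content, had z = -0.05. Fitted trends with base shares were removed before any z was taken, so this value says little about GC content. A trend of another form is not excluded. CTCCCGG, AAATAAA and CGCGCCG passed in that mean (permutation p corrected for all sequences 0.00699, 0.028 and 0.045), so other trends with sequence are present. For repression by the control hairpin, genes with 2 or more matches to GAAGAGC or AAGAGCA, TULP3 left out, lay 0.034 (SE 0.011, one-sided permutation p = 0.0007) above genes with 1 in the mean, but that count takes a site where both sequences overlap as 2 matches and so does not measure the number of sites. With overlapping matches counted once, genes with 2 or more separate sites differed from genes with 1 by 0.002 (SE 0.012, one-sided permutation p = 0.438) in the mean and by 0.001 (SE 0.015, p = 0.465) in XRN2 knockdown. TULP3 has 5 AAGAGCA and 3 GAAGAGC matches, some of them overlapping; whether the control hairpin or both nucleases account for its rise stays open.

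In XRN2 knockdown, 678 genes lying within 10 kb downstream of an expressed gene on the same strand were 0.0854 (log2, SE 0.0274, permutation p = 0.00235) higher than 619 genes whose upstream neighbour lies on the opposite strand; in EXOSC10 knockdown the difference was 0.0151 (permutation p = 0.437), and the direct comparison gave 0.0703 (permutation p = 0.00284). Expression level, GC content and length are argued against as the whole cause, since the difference was 0.0902 (permutation p = 0.00054) after regression on them. The difference was 0.126 (permutation p = 0.00012) where the upstream gene was more abundant than the gene itself, and -0.0806 (permutation p = 0.0355), the opposite direction, where it was less abundant. Reads from transcription past the end of the upstream gene could give such a shift, as XRN2 acts in termination. The shift was 0.12 in XRN2 knockdown replicate 1 and -0.0009 (permutation p = 0.972) in replicate 2, which had the lower XRN2 mRNA, so this explanation and a property of replicate 1 cannot be told apart with 2 libraries.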
